A study of Mus musculus with 7 samples.

How the data were processed

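The series measured messenger RNA in 7 libraries of primary mouse motor neurons: 2 with an empty control lentivirus, 2 with a miR-218 knockdown virus (KD) and 3 with a miR-218 overexpression virus (OE). Groups and replicate numbers were taken from the sample titles. The design text speaks of duplicates, while the titles list 3 OE libraries, and all 3 were used. Per the labels' protocols, motor neurons were purified over a density gradient from dissociated embryonic spinal cord, grown with the trophic factors CNTF and GDNF, and given fluorodeoxyuridine, which blocks division of glia, after 5 days in culture. Per the labels' protocols, single reads of 50 bases were sequenced on 1 lane, base calls were made with CASAVA 1.8.2, reads were mapped with TopHat2 2.0.10 to mouse genome build mm9, and uniquely mapped reads were counted per gene with HTSeq-count 0.6.1p1. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes could not be told apart. Unique mapping leaves out reads shared by near-identical copies, such as some ribosomal protein genes.

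The deposited table held raw counts per gene for the 7 libraries, per the file headers, and these counts of 23366 genes were the values analysed. It also held a block of counts scaled by size factors, which was not used here. The authors' comparisons in the same table gave a signed linear fold change, a log2 fold change, a p-value and an adjusted p-value from DESeq2 1.4.5, per the file headers and the labels' protocols. The authors' deposited log2 fold changes and adjusted p-values were used only to count calls at the stated thresholds and for the correlation with the fit made here, and the authors' signed folds were used to count calls over the fold threshold. Of the genes, 6232 had no count in the 7 libraries, yet the authors' p-values were given for some of them, so the authors' fit may have held further libraries, which were not analysed here. Depth ran from 1591812 to 3360686 counts per library, with the 50 most abundant genes taking 12.9% to 14.2%. The controls were the shallowest group.

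Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter by group (12134 genes kept), and the quasi-likelihood F test with robust dispersion in 1 fit of the 7 libraries with group means (4 residual degrees of freedom, prior degrees of freedom 28.1, biological coefficient of variation 12.5%). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold change over 1.5, the threshold the labels state. All tests were two-sided except the rank among control words, which counted only words as low as the site. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM are counts scaled to a common library total after TMM, as computed by edgeR, given as mean ± SD over the libraries of a group. Counting intervals are exact 95% intervals for a ratio of counts and cover counting error only. The fit was tested on simulated counts with 50 genes changed by each of 4 folds. Of genes changed 1.5-, 2-, 3- and 4-fold it recovered 18%, 64%, 72% and 90% in OE against control (11929 genes), 20%, 54%, 72% and 90% in KD against control (11913 genes), and 16%, 60%, 86% and 86% in OE against KD (11894 genes), with 5, 10 and 8 unchanged genes called.

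Gene sets were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation, the p of which is printed beside each call. The first adjusted p was lost for most lists with the estimated correlation: proliferation, p53, cholesterol synthesis and cytoskeleton kept it in KD, and p53 and cholesterol synthesis in OE. Of 29 lists fixed beforehand 27 had the 3 tested members required: published miR-218 targets, Slit-Robo genes with the miR-218 hosts, motor neuron identity, spinal interneuron markers, neuronal cytoskeleton and axon, potassium channels, sodium and calcium channels, glutamate receptors, GABA and glycine receptors, synaptic vesicle and release, activity-dependent genes, astrocyte and radial glia, oligodendrocyte lineage, Schwann and neural crest, microglia and macrophage, and fibroblast and meningeal markers, proliferation, interferon response, unfolded protein and integrated stress response, p53 and cell death, ALS genes, microRNA machinery, cholesterol synthesis, glycolysis, Hippo pathway and TEAD targets, ribosomal proteins and the mitochondrial respiratory chain. Endothelial or pericyte and red blood cell lists had too few tested members. Adjustment over lists was made within each comparison. Some genes stand in more than 1 list, such as Slc1a2 and Gja1, which are both published targets and astrocyte markers.

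Seed sites were searched in the longest annotated 3' UTR of each gene, from a gene annotation on the same build, mm9. Of the tested genes 11133 (91.8%) had such a 3' UTR. A 7mer-m8 site was AAGCACA, an 8mer AAGCACAA and a 6mer AGCACA. Median log2 fold changes of genes with a site were compared with those of genes with no 6mer, and camera set them against all other tested genes with a 3' UTR. The seed step was tested on simulated data, where a planted shift of -0.15 was found as -0.136. All 16186 words of 7 bases in at least 50 genes were then scored by a regression on 3' UTR length and base composition, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. This search and the CTAACC classes were chosen after the data were seen, and a word planted in simulated data ranked 1.

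The OE and KD fold changes were compared by their correlation and covariance across genes, beside 40 simulations of unchanged groups against the same controls. Genes named in the text followed a rule set before the data were examined, as were the lists, thresholds and tests except where stated. For each comparison the rule took the 8 called genes of greatest rise and of greatest fall with at least 10 CPM in a group and no overlap between groups, up to 3 called members of each list by adjusted p (for a list with none, the 2 of highest expression could be given as values), all tested published targets in OE and KD, the 6 called 8mer genes that fell most in OE and that rose most in KD, up to 6 genes called in opposite directions, and Slit2, Slit3 and the miR-218 genes. Other calls that complete a short list, such as further members of a list where all calls are given, were named after their values were seen. A few genes that met the rule are not named in the text because they are withheld, and the counts of calls still hold them.

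Alternatives were other scalings and filters, DESeq2 1.42.0 and limma-voom in place of edgeR, other thresholds, only the groups compared, the replicate number as a block, each library left out in turn, other site definitions, control words, passenger strands, the shortest in place of the longest 3' UTR, and other set tests. Thinning all libraries to the shallowest, leaving out genes with CTAACC and setting OE and KD against different control libraries were added after the data were seen. Figures were drawn with matplotlib 3.10.9.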

Results

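RNA was sequenced from primary motor neurons isolated from the spinal cord of C57BL/6 mouse embryos and transduced in culture with lentivirus. The series concerns miR-218, a microRNA enriched in motor neurons, in relation to amyotrophic lateral sclerosis (ALS). The 7 libraries fell into 3 groups: 2 from cells given an empty control virus, 2 from cells given a miR-218 knockdown virus (KD) and 3 from cells given a miR-218 overexpression virus (OE). Gene counts summed to 2099714 and 1591812 in the control libraries, 3081800 and 3329184 in KD, and 3360686, 2879382 and 3273026 in OE. Between 13700 and 15016 genes had at least 1 count per library, and 12134 genes were tested. The labels do not say whether libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical. Log2 expression correlated across genes at 0.95 between the controls, 0.971 between the KD libraries and 0.969 to 0.971 within OE. Pairs within a group differed by 2.95 to 3.51 times the counting variance per gene, so no library was taken for a copy of another. The leading principal component carried 36.8% of the variance and placed the controls lowest (-30.2 and -51), the OE libraries between 2.5 and 10.7, and the KD libraries at 27.2 and 31.7. The next component (19.4%) placed control 1 (19.3) beside OE (15.5 to 19) and control 2 (-28.2) beside KD (-18.7 and -22.6). The one after it (15.9%) parted the controls (-35.9 and 15.4).

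The gene targeted by the viruses was examined before other genes. Mir218-1, which encodes a miR-218 precursor, had 107 and 81 counts in the control libraries, 137 and 179 in KD, and 1126, 670 and 938 in OE. Scaled to library size this was 52.1 ± 0.285 CPM (library-scaled counts; SD, n = 2) in control, 47.6 ± 6.89 in KD (n = 2) and 289 ± 54.2 in OE (n = 3). Mir218-1 rose 5.54-fold in OE against control (log2 2.47, SE 0.16, edgeR adjusted p = 3.32e-12) and showed no change past the test in KD (log2 -0.13, SE 0.19, edgeR adjusted p = 0.727). In genome build mm9 it lies on chromosome 5 at 48615181 to 48615290 on the plus strand, inside an intron of Slit2 and overlapping none of its exons. These counts are reads over the precursor region, so they check the OE labels but say nothing of mature miR-218 in KD. The host gene Slit2, which encodes a secreted axon guidance ligand, gave log2 0.27 in OE and 0.27 in KD (edgeR adjusted p = 0.466 and 0.416). Slit3, the host of the other precursor, gave 0.31 and -0.07 (edgeR adjusted p = 0.701 and 0.934), and Mir218-2 had 0 counts in the 7 libraries.

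**Figure D1:**
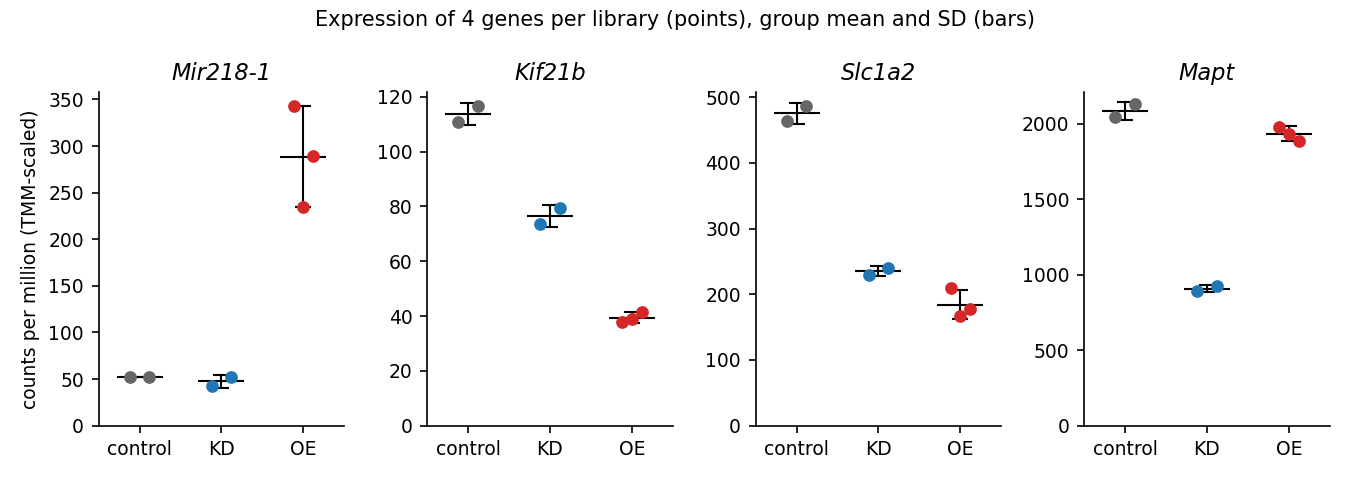
CPM (y axis, TMM-scaled counts) of Mir218-1, Kif21b, Slc1a2 and Mapt in the control, KD and OE libraries; points are libraries and black bars the group mean and SD. Mir218-1 averaged 289 CPM in OE against 52.1 in control, while Mapt averaged 1930 in OE, 2090 in control and 908 in KD.

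The comparison of OE with control asked what raised miR-218 does to transcript levels in these cultures, labelled as motor neurons. Of 14 motor neuron identity genes 8 had enough counts to be tested. Their mean log2 CPM was 2.54 to 3.29 per library, against 5.2 to 5.38 for interneuron markers and 6.08 to 6.68 for astrocyte and radial glia markers. Means of different genes do not measure shares of cells, and the cells in which a change arose were not told apart. Kif21b, a kinesin motor of neurons, fell from 114 ± 4.0 CPM in control (SD, n = 2) to 39.4 ± 2.04 in OE (n = 3), a 2.88-fold decrease (log2 -1.53, SE 0.16, edgeR adjusted p = 8.79e-08). Slc1a2, the main glutamate transporter of astrocytes, fell 2.58-fold from 476 ± 16.0 to 184 ± 22.2 CPM (log2 -1.37, SE 0.10, edgeR adjusted p = 4.64e-11). Some genes of cell division and of the p53 response (13 of 20 and 6 of 16 listed) rose in the same libraries, with Top2a, the topoisomerase of dividing cells, 2.22-fold higher (log2 1.15, SE 0.21) and Eda2r, a TNF receptor family member induced by p53, 3.62-fold higher (log2 1.85, SE 0.26).

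Across all genes, 443 rose and 153 fell in OE against control (edgeR quasi-likelihood test, adjusted p under 0.05 and a fold change over 1.5), so 74.3% of the calls were rises. In the authors' deposited table the same thresholds gave 417 higher and 153 lower, of which 397 and 139 were also called here. The log2 fold changes of that table and of the edgeR fit correlated at 0.97 across 12134 genes, which are not independent replicates. The 8 falls of greatest size among well-expressed genes were Pex5l, a subunit of pacemaker channels (log2 -1.61), Kif21b, Lrrc55, an auxiliary subunit of potassium channels (-1.47), the orphan receptor Gpr153 (-1.45), the cytokine Il17d (-1.44), the membrane protein Itm2c (-1.43), the centrin Cetn2 (-1.40) and Slc1a2. The 8 rises of greatest size were Wisp2, a secreted matricellular protein (log2 2.91, SE 0.52), the chemokine Ccl7 (2.88), Tor3a (2.86), the chemokine-like factor Cklf (2.66), Cdc6, which licenses DNA replication (2.58), Mir218-1 (2.47), the pentraxin Ptx3 (2.34) and the receptor tyrosine kinase Epha2 (2.26). Several of these rises started from few reads: the controls together held 8 counts of Wisp2, 5 of Ccl7, 6 of Tor3a and 6 of Cdc6, and the 95% counting intervals of their ratios ran from 3.85 to 18.3, 3.15 to 23.9, 3.31 to 20.7 and 2.72 to 17.2. The number of rises was 237 without control 2 and 294 without OE 3, and 223 with limma-voom in place of edgeR. The call of Il17d was lost in 6 of 16 alternative settings.

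Genes whose 3' UTR holds a match to the miR-218-5p seed (AAGCACA) were lower in OE. The 1804 genes with a site had a median log2 fold change of -0.108 against 0.031 for the 6677 genes with no 6mer, a difference of -0.139 (camera p = 0.000182; p = 0.00203 with an estimated correlation; two-sided). The 527 genes with an 8mer site (AAGCACAA) differed by -0.205 (camera p = 2.13e-07; p = 0.000612 with an estimated correlation). The difference was -0.129, -0.141 and -0.125 in OE 1, OE 2 and OE 3 taken one by one against the control mean, while control 1 minus control 2 gave 0.031. Of 102 words made of the same bases in another order, 0 lay as low as the seed site (one-sided permutation rank p = 0.00971, the smallest that 102 words can give). The 8mer genes included 36 that fell and 9 that rose, and falls were 6.83% of them against 0.599% of genes without a 6mer (odds ratio 12.2, 95% interval 7.45 to 19.8; Fisher's exact test across genes, two-sided, p = 1.63e-21). Genes with a site had longer 3' UTRs, with a median of 2519 bases against 849. With 3' UTR length and A+U share as covariates the difference of all site genes in OE shrank to -0.079, still past the threshold.

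The 8mer genes that fell most were Pex5l, Kif21b, Gpr153, Itm2c, the phospholipase-domain gene Plcxd2 (log2 -1.35, SE 0.22) and 2010107G23Rik (-1.27, SE 0.23). In the authors' deposited values Pex5l also fell in KD against control (log2 -1.77, DESeq2 adjusted p = 0.000142). It did not differ past the test between OE and KD (0.24, DESeq2 adjusted p = 0.9). In the same deposited values Kif21b fell less in KD (-0.57, DESeq2 adjusted p = 0.00563) than in OE (-1.51). There Gpr153 (-0.33), Itm2c (0.23), Plcxd2 (-0.00) and 2010107G23Rik (-0.41) did not pass in KD. Kif21b carries 2 such sites in its 3' UTR, with the 7 bases AAGCACA at 138072974 to 138072980 and 138073720 to 138073726 of chromosome 1 (mm9, plus strand). Itm2c has these bases at 87804810 to 87804816 of chromosome 1 on the plus strand, and Pex5l at 32849388 to 32849394 of chromosome 3 on the minus strand. Slc1a2 has 6 seed matches in a 3' UTR of 9250 bases on chromosome 2, the outermost at 102622810 to 102622816 and 102630734 to 102630740, and none of them is an 8mer.

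Published miR-218 targets fell as a set in OE. Of the 17 tested members of a list of 20, 7 fell, 1 rose and 9 did not pass (median log2 -0.29; camera adjusted p = 1.49e-05; adjusted p = 0.0955 with an estimated correlation). The falls included Slc1a2, Vopp1 (-1.13), the potassium channel Kcnh1 (-1.08), the heparan sulfate epimerase Glce (-0.78), the Polycomb gene Bmi1 (-0.75) and the Slit receptor Robo2 (-0.62), and the rise was the gap junction gene Gja1 (1.00, SE 0.17). Members that did not pass lay between -0.38 (Rictor) and 0.59 (Onecut2), with Dcc at -0.29, Sfmbt1 -0.26, Bcl11a -0.23, Ikbkb -0.10, Robo1 0.17, Foxp2 0.31 and Tead1 0.46. Adjusted over the list alone the counts were the same, 7 down and 1 up. Kcnh1 may have been drawn by the study from these samples, so its fall is not independent evidence of the list's direction. The calls of Bmi1 and Glce were lost in 9 and 10 of 16 alternative settings, that of Kcnh1 in 3 and that of Pex5l, outside this list, in 1.

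Proliferation genes rose in OE, with 13 of 20 members called higher and 0 lower (median log2 0.98; camera adjusted p = 6.17e-16; adjusted p = 0.0866 with an estimated correlation). Examples were Rrm2, which makes deoxynucleotides (log2 1.02, SE 0.16), the replicative helicase subunit Mcm4 (1.14, SE 0.18) and Top2a. In the p53 and cell death list 6 of 16 members rose and 0 fell (median 0.57; camera adjusted p = 4.23e-09; adjusted p = 0.0468 with an estimated correlation), among them Eda2r, the cyclin Ccng1 (0.91, SE 0.11) and the pro-apoptotic Pmaip1 (1.08, SE 0.15). Of 11 genes of the Hippo pathway and its TEAD targets, 4 rose and 0 fell, including the coactivators Yap1 (2.63-fold) and Wwtr1 (1.18, SE 0.25) and the target Cyr61 (0.81, SE 0.12; list median 0.73; camera adjusted p = 2.66e-06; adjusted p = 0.137 with an estimated correlation). Adjusted over each list alone, 15 proliferation, 6 p53 and 7 Hippo genes rose.

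Markers of non-neuronal cells moved in the same libraries as these groups. Of 14 astrocyte and radial glia markers 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.69; camera adjusted p = 3.73e-05; adjusted p = 0.109 with an estimated correlation). The intermediate filament Vim rose from 932 ± 112 to 1730 ± 129 CPM and the fatty acid binding protein Fabp7 from 1150 ± 139 to 1940 ± 58.1 CPM, and the marker that fell was Slc1a2. Of 9 fibroblast and meningeal markers 2 rose, Fn1 (0.71) and Col1a1 (0.88), in OE (camera adjusted p = 0.0374; adjusted p = 0.459 with an estimated correlation, and with the preset one past the threshold in 4 of 7 fits with a library left out, with 0.14 without control 2). No member was called among 7 oligodendrocyte lineage, 7 Schwann and neural crest and 3 microglia and macrophage markers.

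Genes of cholesterol synthesis were lower as a set in OE (median log2 -0.39 over 18 genes; camera adjusted p = 9.69e-08; adjusted p = 0.0468 with an estimated correlation). Only Srebf2, the transcription factor of the pathway, was called (log2 -0.67, SE 0.20; lost in 6 of 16 alternative settings), with 3 members called when adjusted over the list alone. Of 22 synaptic vesicle and release genes 1 fell, the priming factor Unc13a (-0.70, SE 0.13), and the set lay lower (median -0.16; camera adjusted p = 0.00662; adjusted p = 0.122 with an estimated correlation). The 20 ALS genes had 0 calls, or 1 lower adjusted over the list alone, and a median of -0.15 (camera adjusted p = 0.0374; adjusted p = 0.185 with an estimated correlation, and with the preset one past the threshold in only 3 of 7 fits with a library left out, with 0.0985 without control 2). The 72 ribosomal protein genes had 0 calls and a median of 0.15 (camera adjusted p = 5.56e-05; adjusted p = 0.512 with an estimated correlation, and 0.119 without control 1 with the preset one).

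The other 17 lists did not pass in OE against control (camera adjusted p from 0.0647 to 0.923). Among 35 potassium channel genes Kcnh1 and the M-current subunit Kcnq5 fell (both -1.08), with 3 falls adjusted over the list alone. Cacnb4, a calcium channel subunit, fell among 19 sodium and calcium channel genes (-0.67). The metabotropic receptor gene Grm3 fell (-0.64) and the AMPA receptor gene Gria3 rose (0.65) among 19 glutamate receptor genes, and none of 14 GABA and glycine receptor genes was called. Ret, the receptor component for GDNF, rose among 8 motor neuron identity genes (log2 1.13, SE 0.34, edgeR adjusted p = 0.035), Slc17a6, a vesicular glutamate transporter, fell among 13 interneuron markers (-0.60), and Robo2 fell among 8 Slit-Robo genes. Single calls were also made for Jun in 19 activity-dependent genes (0.78), Bst2 in 14 interferon genes (1.18) and Herpud1 in 18 stress response genes (-0.63). None was made in 12 cytoskeleton and axon, 14 microRNA machinery, 19 glycolysis or 73 respiratory chain genes. Of these calls, that of Ret was lost in 6 of 16 alternative settings and those of Kcnq5, Grm3 and Slc17a6 in 5 each. Median, mean and test differed in sign for Slit-Robo genes (0.03, 0.03, lower), motor neuron identity (0.01, -0.03, higher) and sodium and calcium channels (-0.05, 0.01, lower).

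**Figure D2:**
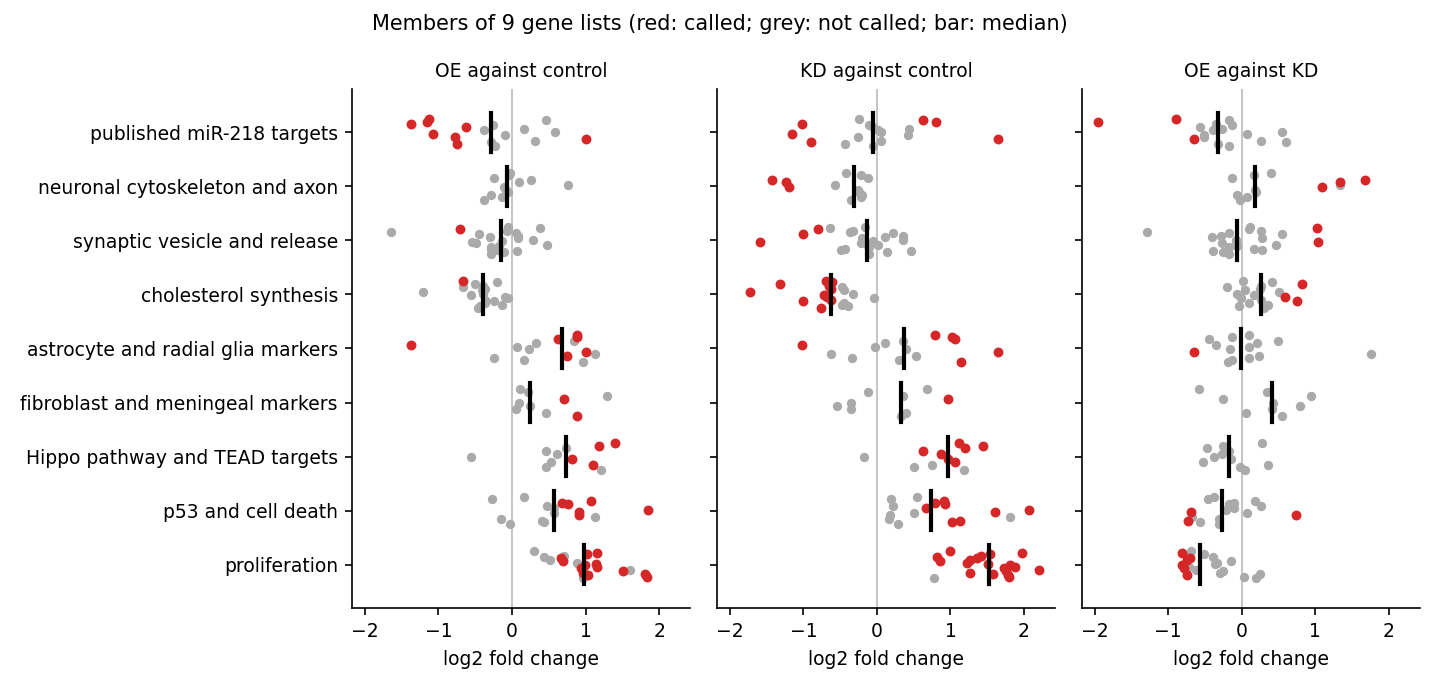
Log2 fold change (x axis) of each tested member of 9 gene lists in the 3 comparisons; red points passed the edgeR thresholds, grey points did not, and black bars are list medians. The median of the proliferation list was 0.98 in OE against control, 1.53 in KD against control and -0.57 in OE against KD.

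The comparison of KD with control asked what follows when miR-218 is targeted for knockdown. The falls included the microtubule-binding protein Mapt, from 2090 ± 60.2 CPM in control to 908 ± 23.2 in KD (SD, n = 2 each; log2 -1.20, SE 0.07, edgeR adjusted p = 2.5e-13). Neurofilament genes Nefm (log2 -1.42, SE 0.12) and Nefl (-1.24, SE 0.17) and the calcium channel subunit gene Cacna2d1 (-1.59, SE 0.12), which fell from 320 ± 5.52 to 106 ± 2.4 CPM, were also lower. Cell division genes were higher, with the mitotic kinase gene Cdk1 3.31-fold above control (38.3 ± 0.224 to 127 ± 4.94 CPM; log2 1.73, SE 0.21). The smooth muscle gene Cnn1 rose 8.23-fold, from 14.3 ± 4.28 to 115 ± 15.1 CPM (log2 3.04, SE 0.25, edgeR adjusted p = 1.18e-10).

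In all, 849 genes rose and 571 fell in KD against control by the same edgeR thresholds, so 59.8% of the calls were rises. The authors' deposited table gave 778 and 544, of which 752 and 518 were called here, with a correlation of log2 fold changes of 0.974 across genes. After Cd34, a surface marker of vascular progenitors, the rises of greatest size were Cdca2, a mitotic phosphatase regulator (log2 3.23, SE 0.60), tropomyosin Tpm2 (3.11), Gareml (3.06), Cnn1, 1810011O10Rik (3.02), the methionine sulfoxide reductase Msrb3 (2.95) and the actin-binding Lmod1 (2.89). Cd34 had 86 counts in KD and 2 in control, a ratio of 24.8 per total count with a 95% counting interval of 6.65 to 208. The controls together held 6 counts of Cdca2, 5 of Tpm2, 5 of Gareml, 5 of 1810011O10Rik and 6 of Lmod1, with intervals of 4.48 to 28.1, 3.94 to 30.2, 3.69 to 28.4, 3.64 to 28.1 and 3.55 to 22.6, and the call of Tpm2 was lost without control 1. The falls of greatest size were the neurotrophin receptor gene Ngfr (log2 -2.88, SE 0.38), the peptide hormone gene Trh (-2.80, SE 0.65), Pcid2 (-2.26), the Wnt agonist Rspo2 (-2.20), Rasgrp1, which activates Ras (-2.20), the amino acid transporter Slc7a8 (-2.18), 2900011O08Rik (-2.13) and Zfp846 (-2.07). Without KD 2, 486 genes rose.

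Genes with miR-218 seed sites showed no shift past the test as a set in KD. The 1804 genes with a site differed from those without a 6mer by -0.023 (camera p = 0.459; p = 0.23 with an estimated correlation), and the 8mer genes by -0.012 (camera p = 0.441; p = 0.204 with an estimated correlation). The -0.023 had no stable size or sign. It was -0.068 without KD 2, -0.067 without control 2 and -0.014 without control 1. It turned to 0.033 with 3' UTR length and A+U share as covariates and to 0.007 against control words. Of the reordered control words, 62 of 102 lay as low (one-sided permutation rank p = 0.612). Falls were nonetheless more frequent among genes with a site, 6.15% against 4.28% of genes without a 6mer (odds ratio 1.47, 95% interval 1.16 to 1.84; Fisher's exact test across genes, two-sided, p = 0.00132), and among 8mer genes (odds ratio 1.49, Fisher's exact p = 0.0466), with no adjustment for 3' UTR length. Among 8mer genes 33 fell and 32 rose, and those that rose most were Plekha4 (log2 2.02, SE 0.58), the phosphatase Ppm1m (1.99), Prrg3 (1.99, SE 0.31), the cytokinesis gene Cep55 (1.92), Itpripl1 (1.92) and Mdfic (1.86). The call of Plekha4 was lost in 4 of 16 alternative settings, over which its log2 ran from 1.32 to 4.16, and that of Mdfic in 3. The difference from OE was tested directly by the comparison of OE with KD given further on.

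A different word marked the genes that fell in KD. The word CTAACC, chosen after the values were seen, was in the 3' UTR of 302 of the 537 genes that fell and had a 3' UTR (56.2%), against 12.3% of those that rose and 19.3% of those not called. Genes with the 8mer TCTAACCA differed by -0.264 from genes without CTAACC, those with the 7mers TCTAACC and CTAACCA by -0.245 and -0.236, and those with the 6mer alone by -0.129. Calls lower in KD were 16.91% of the 278 8mer genes against 2.66% of genes without the word (odds ratio 7.43, Fisher's exact test across genes, two-sided, p = 2.7e-22). Among 16186 words of 7 bases, TCTAACC and CTAACCA ranked 1 and 2 from the lowest in KD (partial t -11.7 and -11.3 with 3' UTR length and base composition in the model) and gave -1.4 and 0.1 in OE. In OE falls were somewhat more frequent among the 8mer genes (2.52% against 1.15%, odds ratio 2.23, Fisher's exact p = 0.0472) and the TCTAACC 7mer genes (odds ratio 2.04, Fisher's exact p = 0.0347). Both words occur in miR-218-5p itself (UUGUGCUUGAUCUAACCAUGU), at bases 11 to 17 and 12 to 18. Mapt carries CTAACC at 104189641 to 104189646, 104190495 to 104190500 and 104191547 to 104191552 of chromosome 11, Cacna2d1 at 15879672 to 15879677 of chromosome 5 and Ngfr at 95431559 to 95431564 of chromosome 11 (mm9). Among the seed 8mer genes that fell most in OE, Pex5l holds TCTAACC, and Kif21b and Plcxd2 hold CTAACC. Of these, Plcxd2 did not fall past the test in KD. Gpr153, Itm2c and 2010107G23Rik do not hold the word. Slc1a2, with seed matches but no seed 8mer, also holds CTAACC.

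**Figure D3:**
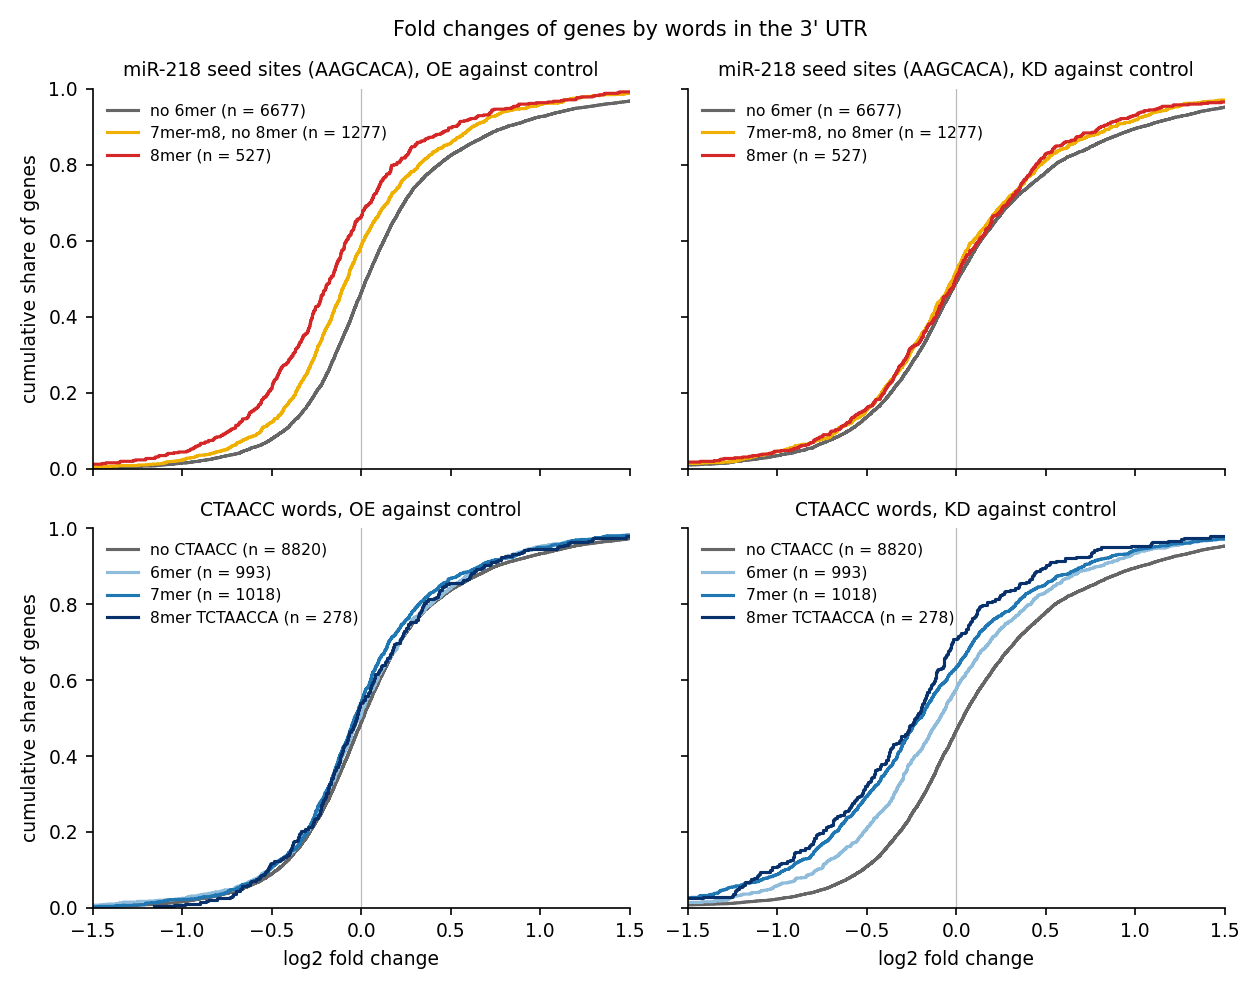
Cumulative share of genes (y axis) by log2 fold change (x axis) for classes of miR-218 seed sites (top) and of CTAACC words (bottom), in OE and KD against control. The 527 genes with a seed 8mer differ in median by -0.205 in OE and -0.012 in KD, and the 278 genes with TCTAACCA by -0.264 in KD and -0.037 in OE.

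Of 12 neuronal cytoskeleton and axon genes 3 fell in KD, Mapt, Nefm and Nefl (median log2 -0.30; camera adjusted p = 2.71e-09; adjusted p = 0.0282 with an estimated correlation). Mapt was the only 1 of these 3 with CTAACC in its 3' UTR. Of 22 synaptic vesicle and release genes 3 fell, Sv2a (-1.59, SE 0.29), Syp (66.5 to 33.0 CPM) and Unc13a (-0.80), or 4 adjusted over the list alone (median -0.14; camera adjusted p = 0.0348; adjusted p = 0.165 with an estimated correlation). In the ALS list of 20 genes the mitochondrial Chchd10 fell (-0.83, SE 0.17) and the annexin Anxa11 rose (2.04, SE 0.59), with a median of -0.16 (camera adjusted p = 0.0348; adjusted p = 0.165 with an estimated correlation). The word was in 2 of the 3 synaptic genes that fell and in Chchd10. The synaptic and ALS sets did not pass without control 2 (camera adjusted p = 0.0944 and 0.0655). They passed in 5 and 6 of 7 fits with a library left out, and did not pass with CTAACC genes removed (camera adjusted p = 0.225 and 0.0697). Cholesterol synthesis genes fell, 11 of 18, such as Cyp51 (-0.76, SE 0.11) and Sqle (-0.61). Their list median was -0.62 (camera adjusted p = 5.06e-11, and 0.0282 with an estimated correlation). CTAACC was in 4 of these 11, but not in Cyp51 or Sqle.

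In the same KD libraries 19 of 20 proliferation genes rose (median log2 1.53; camera adjusted p = 5.51e-22; adjusted p = 0.0358 with an estimated correlation), including Cdk1, Rrm2 (1.54) and Top2a (1.97). In the p53 and cell death list 8 of 16 rose, such as Bax (1.02, SE 0.11), Bbc3 (1.13) and Eda2r (2.07), and 0 fell (median 0.73; camera adjusted p = 6.31e-09; adjusted p = 0.0282 with an estimated correlation). Of 11 Hippo pathway genes 7 rose, or 9 adjusted over the list alone, with Wwtr1 at 1.44, Ctgf 1.06 and Cyr61 0.96 (median 0.96; camera adjusted p = 5.06e-06; adjusted p = 0.165 with an estimated correlation). Astrocyte and radial glia markers showed 5 rises and 1 fall of 14, with Gja1 at 1.64 and Vim at 0.79, while Slc1a2 fell by 1.02 on the log2 scale (median 0.37; camera adjusted p = 0.00077; adjusted p = 0.165 with an estimated correlation).

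Published miR-218 targets did not move as a set in KD (camera adjusted p = 0.963), with 3 rises and 3 falls of 17, the same adjusted over the list alone. The rises included Gja1 and Tead1 (0.63, a call lost in 11 of 16 alternative settings), and the falls Kcnh1 (-1.16), Slc1a2 and the netrin receptor gene Dcc (-0.90). The other 11 lay between -0.43 (Bmi1) and 0.44 (Robo1), with Ikbkb at 0.42, Glce -0.26, Vopp1 -0.25, Sfmbt1 -0.11, Robo2 -0.05, Bcl11a -0.05, Rictor 0.01, Foxp2 0.06 and Onecut2 0.06. This list is 1 of 19 that did not pass in KD (camera adjusted p from 0.0739 to 0.968).

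Of 35 potassium channel genes 6 fell and 0 rose in KD, such as Kcnh1 and Kcnd3 (-0.91). Of 19 sodium and calcium channel genes 3 fell, Cacna2d1, Cacna2d2 (-1.42) and Scn3a (-0.73), each with CTAACC, and 2 rose (4 and 2 adjusted over the list alone). The glutamate receptor genes Grm7 fell (-0.64) and Gria3 rose (0.62), and Gabrb2 rose (0.83) among the GABA and glycine receptors. Ret rose (1.09) among motor neuron identity genes, Sst (-0.90) and Slc17a6 (-0.65) fell among interneuron markers, and Robo3 rose (1.97) and Srgap2 fell (-1.02) among Slit-Robo genes. Other calls included Ngfr, lower in the Schwann and neural crest list, Cnp, higher among oligodendrocyte markers (2.20), Fn1, higher among fibroblast markers (0.97), Bst2, higher in the interferon list (1.14), Egr1 (0.70), Phgdh in the stress response list (0.72), Aldoa in glycolysis (-0.77), and Uqcrb (-0.78) and Cox6b2 (1.51) in the respiratory chain. The call of Cox6b2 was lost in 9 of 16 alternative settings, that of Cnp in 7 of 14, those of Ret and Robo3 in 6 of 16 and that of Phgdh in 5. Ribosomal protein, microRNA machinery and microglia genes had 0 calls. Median, mean and test differed in sign for interneuron markers (0.06, -0.07, lower), Slit-Robo genes (-0.06, 0.08, lower), activity-dependent genes (0.16, 0.03, lower), glycolysis (0.04, 0.02, lower) and the respiratory chain (-0.03, 0.01, lower).

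OE and KD were also compared with each other, which does not use the control libraries for the means. Nefm was 3.19-fold higher in OE than in KD (475 ± 64.1 against 149 ± 9.71 CPM; n = 3 and 2; log2 1.67, SE 0.11, edgeR adjusted p = 2.6e-12), Mapt 2.13-fold (log2 1.09, SE 0.07) and Cacna2d1 2.92-fold (1.54, SE 0.11). In total 356 genes were higher and 287 lower in OE than in KD (edgeR, same thresholds), and the authors' deposited table gave 357 and 269, of which 338 and 244 were called here (correlation 0.99 across genes). The greatest differences upward were Mir218-1 (log2 2.60, SE 0.15), the protease Pappa (2.21), Ngfr (2.19), 2900011O08Rik (2.17), the chemokine Ccl20 (2.10), the peptide genes Nts (1.96) and Calca (1.89), and the serpin Serpina3n (1.85). Those downward included Prrg3 (log2 -2.89, SE 0.27), which carries a seed 8mer, the adenylyl cyclase Adcy7 (-2.64), Mfsd4 (-2.44), Marveld1 (-2.33), Stbd1 (-2.15), Amn (-2.05) and Haus4 (-1.98). The number lower was 132 without KD 1, 110 without KD 2 and 187 without OE 1, and 154 with DESeq2.

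Genes with a miR-218 seed site were lower in OE than in KD by -0.107 (camera p = 0.00862; p = 0.00745 with an estimated correlation), and 8mer genes by -0.172 (camera p = 6.54e-05; p = 0.00148 with an estimated correlation). Calls lower in OE were 9.87% of 8mer genes against 1.71% of genes with no 6mer (odds ratio 6.3, 95% interval 4.39 to 8.95). With any 6mer or with 7mer-A1 sites in place of the longer sites the shift did not pass with the preset correlation (-0.056 and -0.046, camera p = 0.143 and 0.602). With an estimated correlation any 6mer passed (camera p = 0.0137) and 7mer-A1 sites did not (camera p = 0.236). CTAACC was in the 3' UTR of 66.2% of genes higher in OE than in KD, against 18.3% of those lower and 19.2% of those not called.

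In this comparison the cytoskeleton and axon list was higher in OE, with 3 of 12 called, Nefm, Nefl and Mapt, or 4 adjusted over the list alone (median log2 0.18; camera adjusted p = 3.43e-09; adjusted p = 0.0845 with an estimated correlation). Cholesterol synthesis genes were higher, 3 of 18 called, Sc5d (0.82), Fdps (0.75) and Idi1 (0.59; median 0.25; camera adjusted p = 0.00131; adjusted p = 0.166 with an estimated correlation). Ribosomal protein genes (0 of 72 called, median 0.12; camera adjusted p = 0.000273) and respiratory chain genes (1 of 73, Uqcrb, 0.83; median 0.11; camera adjusted p = 0.00854, or 0.0746 without OE 2) did not pass with an estimated correlation (adjusted p = 0.789 and 0.709). Proliferation genes were lower in OE than in KD, 6 of 20 called, among them Top2a (-0.82), Cdk1 (-0.79) and Mcm7 (-0.75), or 9 adjusted over the list alone (median -0.57; camera adjusted p = 2.13e-06; adjusted p = 0.323 with an estimated correlation). Published targets were lower, with 3 of 17 called, among them Vopp1 (-0.89) and Gja1 (-0.65), and adjusted over the list alone 3 lower and 1 higher (median -0.32; camera adjusted p = 0.000124; adjusted p = 0.166 with an estimated correlation).

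The other 21 lists did not pass in OE against KD (camera adjusted p from 0.0902 to 0.931). Called members included Cacna2d1, Cacna2d2 (1.36), Scn3a and Scn9a upward and Cacnb4 (-1.04) and Scn2b downward among sodium and calcium channels, of which Scn9a and Scn2b were named after their values were seen. Sv2a (1.04) and Vamp1 (1.02) were higher among synaptic vesicle genes, Chchd10 (0.86) in the ALS list, Sst (0.78) among interneuron markers, Srgap2 (0.62) among Slit-Robo genes, Aldoa (0.64) in glycolysis and Ngfr in the Schwann and neural crest list. The receptor genes Grm7 (0.61), Grik3 (-0.64) and Gabrb2 (-0.61), the interferon gene Ifit2 (-1.57), the p53 list genes Ccng1 (0.73), Bbc3 (-0.73) and Ddit4l (-0.69), Mbp (-1.05) among oligodendrocyte markers and Gja1 among astrocyte markers were also called. The calls of Gabrb2, Ddit4l and Mbp were lost in 8, 7 and 6 of 16 alternative settings. Potassium channel, motor neuron identity, activity-dependent, microglia, fibroblast, stress response, microRNA machinery and Hippo genes had 0 calls. Median, mean and test differed in sign for synaptic vesicle genes (-0.07, 0.03, higher), Slit-Robo genes (0.08, -0.05, higher), astrocyte markers (-0.02, 0.07, lower), ALS genes (-0.03, 0.02, higher) and microRNA machinery (-0.07, 0.01, lower).

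The OE and KD changes were set against each other to see whether they ran in opposite directions. Only 5 genes were called in opposite directions. Those higher in OE and lower in KD were Calca, which encodes a calcitonin gene-related peptide (log2 1.02 and -0.87), the adhesion molecule Vcam1 (1.07 and -0.66), the ferroxidase Cp (0.64 and -1.02) and the kinase Dgkk (0.75 and -0.66). Far more genes were called in the same direction, 336 higher in both and 58 lower in both, where independent lists would share 31 and 7.2. The 2 sets of log2 fold changes correlated at 0.74 across genes, which are not independent replicates, and the correlation ran from 0.65 without KD 2 to 0.87 without control 1 and was 0.64 with no filter on low counts. Because both comparisons use the same 2 controls, unchanged groups simulated against those controls 40 times gave a mean correlation of 0.63 (at most 0.65). The simulations gave on average 0 calls in OE and 0.1 in KD, so their 0 shared calls were nearly fixed in advance. They held no difference particular to the control cultures, and so cannot say how many shared calls such a difference would give. The main correlation lay above the 40 simulated ones. No unchanged groups were simulated for the other settings, so the 0.65 without KD 2 and the 0.64 with no filter could not be set against chance. The observed covariance was 0.333 against 0.094 in the simulations, a difference of 0.239. With each comparison set against a different control library, a check added after the data were seen, the correlation was 0.29 or 0.26 and the covariance 0.228 or 0.219. With 1 control library used for both comparisons the correlation was 0.82 (control 1) and 0.88 (control 2), and the covariance 0.535 and 0.864. Each of these rests on 1 control library per comparison, so part of the correlation came from the shared controls. Part of the excess of shared calls may come from them too.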

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

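The alternatives with thinned libraries, with CTAACC genes left out and with split controls were chosen only after the results were seen. The numbers of calls stayed within 1.5 times the reported ones with other scalings, other filters on low counts, only the groups compared, an adjusted p under 0.1 and thinning to 1591812 counts per library. Exceptions were 154 genes lower in OE than in KD with DESeq2, 223 higher in OE against control with limma-voom, and, with no fold minimum, 316 lower in OE, 877 lower in KD and 567 higher in OE than in KD; the last 3 follow from the looser criterion, and for the others the cause was not tested. With CTAACC genes left out 269 genes were lower in KD and 129 higher in OE than in KD, because called genes were removed.

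With 1 library left out at a time, 237 to 434 genes were higher in OE against control (237 without control 2, 294 without OE 3), 103 to 172 lower in OE, 486 to 833 higher in KD (486 without KD 2), 396 to 567 lower in KD, 239 to 410 higher in OE than in KD, and 110 to 356 lower in OE than in KD (110 without KD 2, 132 without KD 1, 187 without OE 1). The seed-site difference ran from -0.156 to -0.134 in OE, -0.068 to -0.014 in KD and -0.12 to -0.09 in OE against KD. Lists numbered 5 to 7 higher and 3 to 6 lower in OE, 4 to 4 higher in KD, and 3 to 4 higher and 2 to 3 lower in OE against KD. Lists lower in KD numbered 2 to 5 (2 without control 2), and the correlation of OE and KD fold changes ran from 0.65 to 0.87 (0.87 without control 1) and was 0.64 with no filter on low counts. With the controls split it was 0.29 (OE against control 1, KD against control 2) and 0.26 (the reverse). The comparisons then share no library, and each rests on 1 control library. With 1 control library used for both it was 0.82 (control 1) and 0.88 (control 2). All of these rest on 1 control library per comparison, so the lower correlation with split controls goes with the lack of a shared library. The covariance was 0.535 (control 1) and 0.864 (control 2) with a shared library, and 0.228 and 0.219 without. Where a setting left 1 library in a group, that sample was assumed to vary like the other groups, and the cause was not tested.

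The replicate numbers of the labels did not pair the libraries, since deviations from group means correlated at -0.05 to 0.03 between libraries of the same number. With the replicate number as a block 464 genes were called in OE against control (421 of them called without it), 1395 in KD and 556 in OE against KD.

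The lower seed-site genes in OE kept their direction and side of the threshold with few exceptions. These were 7mer-A1 sites (-0.088, camera p = 0.113, but 0.0133 with an estimated correlation) and the passenger strands. The passenger strands miR-218-1-3p (-0.037) and miR-218-2-3p (-0.03) test other words. The difference shrank to -0.079 with 3' UTR length and A+U share as covariates and to -0.072 with any 6mer, both past the threshold. In OE against KD any 6mer (-0.056), 7mer-A1 sites (-0.046) and the passenger strands (0.012 and 0.02) did not pass. In KD the small negative difference turned to 0.033 with 3' UTR length and A+U share as covariates and to 0.007 against control words, none past the threshold. With an estimated correlation the lists that passed were 1 higher and 1 lower in OE, 2 and 2 in KD, and 0 and 0 in OE against KD. For lists lower in KD, fry gave 8, thinning 2 and leaving out CTAACC genes 2, and 4 lists were lower in OE than in KD without those genes; the cause was not tested. The genes named in the text gave 3582 values on the same side of the thresholds over all alternatives, 227 that no longer passed, 2 that newly passed and 0 of opposite sign past the test. Simulated 1.5-fold changes, which lie at the fold threshold, were recovered for 16% to 20% of genes and 2-fold changes for 54% to 64%, so an uncalled gene is not shown to be unchanged.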

Other observations

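The gene groups of the next paragraph and the tests of explanations in this part were chosen only after the results were seen, except that the bound for the test of a lower share of neurons was written before its result.

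Several contractile genes rose in OE and in KD. Of 10 such genes, picked by hand and not tested for enrichment, 7 were higher in OE and 9 in KD against control, and 5 were lower in OE than in KD (edgeR thresholds as in the report). Over all 12134 genes 443 and 849 were higher. Acta2, the smooth muscle actin, had log2 fold changes of 1.25 in OE and 2.23 in KD (edgeR adjusted p = 7.96e-08 and 2.68e-13), and Tagln 0.95 and 1.76. Myl9 gave 1.49 and 2.19 and Cald1 1.30 and 1.57, while Tpm1 did not pass in either (0.31 and 0.35), nor Tpm2 and Lmod1 in OE. Secreted neuropeptide genes went several ways: of 10, 4 fell in KD (Trh -2.80, Nts -1.81, Sst -0.90 and Calca -0.87) and Penk, the enkephalin precursor, rose (1.42, edgeR adjusted p = 2.41e-05). In OE Calca (1.02) and Adcyap1 (0.59) rose. Calca, Nts, Sst and Adcyap1 (1.15) were higher in OE than in KD, and Penk was lower (-0.78, edgeR adjusted p = 0.00446).

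For the CTAACC words in the 3' UTRs of genes that fell in KD, 3' UTR length and base composition were examined first. TCTAACC and CTAACCA gave a partial t of -11.7 and -11.3 with 3' UTR length and A+U share in the model. Words of the same bases in another order, without those that hold CTAACC, reached at lowest -4.3. TCTAACC and CTAACCA were chosen as the lowest of all words, so that the others lay above them was fixed in advance. The size of the gap was not, and it argues against length and base composition as the whole cause. A lower share of neurons in KD as the whole cause was examined among genes that rose in OE. Those with CTAACC were also lower in KD than those without (difference of medians -0.37, two-sided permutation p = 3e-05 from 100000 permutations). In OE their difference was -0.09. This argues against that cause only if the genes that rose in OE are not neuronal, which was not shown. The test made no adjustment for 3' UTR length. Also open is an RNA antisense to miR-218, as a knockdown virus could make, acting through its own seed. The words are part of miR-218 itself, and the shift deepened from the 6mer (-0.129) to the 8mer (-0.264). The partial t of TCTAACC was weaker in coding sequence (-4.3), where 462 genes held it against 799 in 3' UTRs. It still ranked 4 from the lowest of 16380 coding words in KD, and 2 from the highest in OE against KD. Against the simplest form of such an RNA, AACCATG, the word that pairs with bases 2 to 8 of a full antisense of miR-218, gave only -2.7 (rank 103) in KD. It gave 4.0 (rank 26 from the highest) in OE against KD, and the neighbouring TAACCAT gave -5.2 (rank 9) in KD. Where such an RNA would begin was not tested, and the sequence of the construct is not in the sources used here. If such an RNA was made, part of the KD change may not come from lower miR-218. This biological explanation was not tested because mature miR-218 was not measured.

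Of the proliferation, p53 and Hippo lists 13 of 20, 6 of 16 and 4 of 11 genes were higher in OE and 19, 8 and 7 in KD, although the viruses were labelled for opposite changes of miR-218 (with an estimated correlation, adjusted p = 0.0866, 0.0468 and 0.137 in OE and 0.0358, 0.0282 and 0.165 in KD). Lower depth of the controls is argued against: with all libraries thinned to the shallowest, 317 genes were higher in both, against 336. A larger share of non-neuronal cells in the OE and KD cultures than in those with the empty virus may account for part of it. Genes with the site word of miR-124, a neuronal microRNA, were the highest of all words in both comparisons (partial t at least 8.5). This word was chosen after the data were seen, so its rank is not independent support. Genes with it differed from the rest in median by only 0.06 in OE and 0.083 in KD. The astrocyte list lay above both controls in 5 of 5 libraries, though Slc1a2 fell in both and Aqp4 (-0.24 and -0.34) did not rise. A property of the 2 control cultures cannot be told apart from an effect of the viruses for what OE and KD share, since both comparisons rest on those libraries. Proliferation genes were lower in OE than in KD (camera adjusted p = 2.13e-06, past the threshold in 7 of 7 fits with a library left out; adjusted p = 0.323 with an estimated correlation), which a property of the controls alone would not give, while the p53 and Hippo lists did not pass there (camera adjusted p = 0.138 and 0.294; 0.498 and 0.789 with an estimated correlation), and a response to changed miR-218 in either direction was not tested.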
